A study of Mus musculus with 16 samples.

How the data were processed

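The series holds 16 expression arrays, 4 for each of 4 CD8 T-cell subsets sorted from spleens of mice that carried transferred Eµ-TCL1 leukemia cells for 6 weeks. Per the labels' protocols, RNA was isolated with an RNeasy Micro kit, amplified and labelled with biotin by a WT Pico kit, and hybridised to Affymetrix Mouse Gene arrays of the ST type. Per the submitters' processing notes, Affymetrix Power Tools was used; its version, the summarisation method and the annotation release are not given in the sources used here. The values are log2 expression per probe set, as deposited by the authors after summarisation of the probes on a common scale across arrays; the base was read from their range, 2.347 to 14.125. The array medians lay between 6.394 and 6.489, and no pair of arrays was identical. The labels number the arrays of each subset from 1 to 4 and do not say whether arrays of a number, or of a subset, come from separate mice, so the p-values measure only the spread between these samples.

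The file holds 41345 probe sets. The platform annotation gives 1 gene symbol for 23521 of them, several for 1814 and none for 16010. Symbols were checked against RefSeq through Entrez identifiers, which matched 23328 and changed none. Probe sets with several symbols or none were not used here, and for the 1082 genes with more than 1 probe set the one with the highest mean over the 16 arrays stood for the gene, which left 22180 genes. No filter on dim genes was applied. The files carry no detection calls or background level, so a gene near the lower end of the scale can be absent, and log2 differences of dim genes are compressed. The median standard error of a log2 difference between 2 subsets was 0.104.

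All 16 arrays were fitted together with limma (version 3.58.1 in R 4.3.3), lmFit with a mean per subset and no block, followed by eBayes. The 6 pairs of subsets were compared, and a gene was called changed at a Benjamini-Hochberg adjusted p under 0.05 over all genes of that comparison. Counts of genes changed at least 2-fold add an absolute log2 difference of 1 or more. Principal components and Pearson correlations used all genes.

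Gene lists written before the data were seen were tested with limma camera at its preset correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the 29 lists of a comparison. They were inhibitory receptors, exhaustion-associated transcription factors, naive and quiescence genes, progenitor-exhausted genes, cytotoxic effector molecules, effector and short-lived effector genes, central memory genes, killer lectin-like receptors, chemokines, chemokine receptors, cytokine receptors, costimulatory receptors, tissue-residency genes and TCR-induced early genes. Further lists were mitosis, DNA replication, glycolysis, oxidative phosphorylation, cholesterol synthesis, interferon-stimulated genes, ribosomal proteins, heat shock and unfolded protein response, apoptosis regulators, and sort markers and T-cell identity. The last 5 hold markers of other cells: B cells and CLL cells, CD4 and regulatory T cells, myeloid and dendritic cells, erythroid cells and platelets, and natural killer, gamma-delta and innate-like T cells. For each list the members past the threshold were counted over all genes and adjusted over the list alone.

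Genes are named by a rule fixed beforehand. For each comparison these are the 10 with the largest rise and the 10 with the largest fall among genes past the threshold whose arrays do not overlap between the 2 subsets. For the 2 comparisons against memory the first 3 of each are named. Predicted loci, small RNAs and antigen receptor segments were left out of this ranking. To these come the sort genes Cd44, Il7r and Pdcd1, and up to 4 members per list with the smallest adjusted p.

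The spread of T-cell receptor variable segments was measured as the mean absolute deviation of an array from its subset mean over all Trav and Trbv genes with a probe set of their own. Each other subset was set against naive with an exact two-sided permutation test of 4 against 4 arrays, Benjamini-Hochberg adjusted over the 3 tests. The deviation was also ranked among 10000 random lists of genes matched on mean expression.

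The pipeline was tested on simulated data drawn with the mean and the residual SD of each gene, to which known changes were added in the PD-1hi arrays. For PD-1hi against PD-1int it recovered 27 of 50 genes changed by a log2 of 0.5 and 50 of 50 changed by 1, with 11 false calls among 21950 unchanged genes. A shifted list had a camera p of 1.80e-26 and an unchanged list 0.568.

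Alternatives tried were a replicate block, a fit of only the 8 arrays compared, a filter that left out the 40% dimmest genes, the mean of a gene's probe sets, quantile normalization, median centring, eBayes with trend and robust settings, array weights, and leaving out each array in turn. For lists, camera with an estimated correlation, camera on ranks and fry, which tests whether a list's genes move on balance one way and compares them with no other genes, were added. Each comparison was also repeated on all 35 splits of its 8 arrays into 4 and 4. Tables were prepared with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and figures drawn with matplotlib 3.10.9.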

Results

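RNA was measured in CD8 T cells, the cytotoxic lymphocytes that kill infected and transformed cells, from the spleens of female C57BL/6 mice. The mice carried leukemia cells transferred from Eµ-TCL1 mice, a transgenic model of chronic lymphocytic leukemia (CLL), a cancer of B cells. Spleens were taken 6 weeks after transfer, and each CD8 population was divided by flow cytometry into 4 subsets. Naive cells had high CD127, the receptor chain for interleukin 7, and low CD44, an adhesion receptor that rises once a T cell has met antigen. Memory cells had high CD127 and high CD44. The 2 effector subsets had low CD127 and intermediate to high CD44, and were separated by intermediate (PD-1int) or high (PD-1hi) surface PD-1, an inhibitory receptor. Each subset was hybridised to 4 whole-transcript expression arrays, 16 in all, and each array is named by its subset and its replicate number from 1 to 4. A single annotated probe set stood for each of 22180 genes. The sort gates make each pair of subsets a comparison: what separates antigen-experienced from naive cells in a leukemic spleen, and what separates effector cells with more PD-1 from those with less.

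The 4 subsets formed 4 separate groups of arrays. The first principal component held 58.0% of the variance over all genes and ran from naive through memory and PD-1int to PD-1hi, and the second, with 12.2%, set memory apart. Arrays of a subset correlated with a mean Pearson r, taken across genes, of 0.991 in naive, 0.993 in memory, 0.992 in PD-1int and 0.991 in PD-1hi. Between subsets the mean r was 0.988 for PD-1int with PD-1hi, 0.980 for naive with memory and 0.949 for naive with PD-1hi. Genes are not independent replicates, so these r values describe the arrays only. The median log2 value of an array lay between 6.39 and 6.49.

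**Figure D1:**
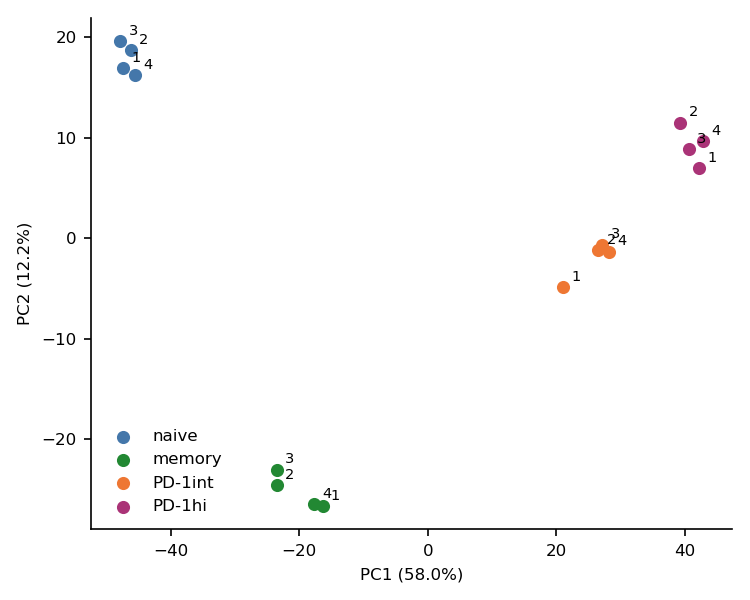
Principal components of the 16 arrays over 22180 genes, with the first component (58.0% of the variance) on the x axis and the second (12.2%) on the y axis, both in arbitrary units. Each point is 1 array, coloured by subset and marked with its replicate number, and the 4 subsets do not overlap.

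The number of genes that changed grew from memory to PD-1hi when each subset was set against naive. Memory differed from naive in 2601 genes, PD-1int in 5037 and PD-1hi in 6020 (limma, Benjamini-Hochberg adjusted p under 0.05). Of these, 422, 1028 and 1373 changed at least 2-fold. PD-1hi differed from PD-1int in 734 genes, 303 higher and 431 lower in PD-1hi, of which 105 changed at least 2-fold; in a fit of those 8 arrays alone 291 were higher and 291 lower. Without PD-1int replicate 1 the count for PD-1hi against PD-1int was 470, and without PD-1hi replicate 4 it was 474. Values given after a gene below are log2 differences ± the standard error of the limma fit, with n = 4 arrays per subset. A gene is said to rise, fall or change only where its limma adjusted p over all genes was under 0.05; every adjusted p below is Benjamini-Hochberg adjusted. Genes named here outside the ranking rule given with the methods, among them the exceptions of a gene list and the markers that did not pass, were chosen after their values were seen. Gene lists were fixed before the data were seen; the p of a list is that of camera with a preset correlation, Benjamini-Hochberg adjusted over the 29 lists of a comparison. An estimated correlation often gave far larger p. Both values are given where only the preset passed and for cell-cycle lists against naive. Where both passed but camera on ranks or without the 40% dimmest genes did not, those are added. The list of sort markers and T-cell identity is left out of the text, since it holds the genes of the gates; it is 1 of the 19 lists that passed in PD-1int against naive. Lists that passed with the preset numbered 16 in memory against naive, 19 in PD-1int against naive, 17 in PD-1hi against naive and 13 in PD-1hi against PD-1int, and with an estimated correlation 10, 14, 11 and 8. In PD-1int and PD-1hi against memory 17 and 20 passed, and 9 and 6 with an estimated correlation.

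**Figure D2:**
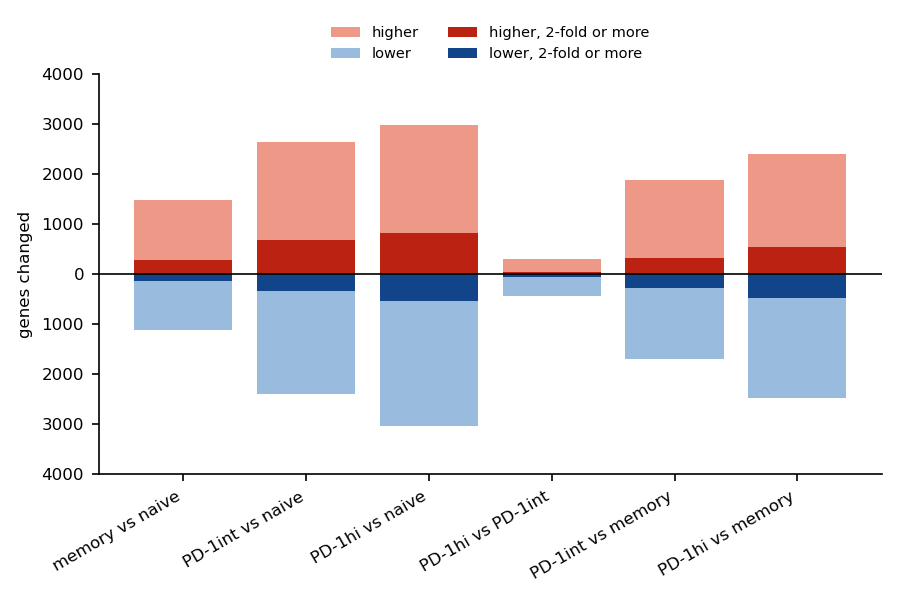
Number of genes that were higher (upward bars) or lower (downward bars) in the first-named subset of each of the 6 comparisons, at a limma Benjamini-Hochberg adjusted p under 0.05 (pale bars) and with a change of at least 2-fold as well (dark bars). PD-1hi against naive had the most, 2981 higher and 3039 lower, and PD-1hi against PD-1int the fewest, 303 and 431.

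The genes behind the sort markers followed the gates. Il7r, which encodes CD127, had a log2 value of 12.97 ± 0.07 in naive, 12.57 ± 0.08 in memory, 7.49 ± 0.33 in PD-1int and 4.91 ± 0.54 in PD-1hi (mean ± SD, n = 4). Cd44 lay at 6.07 ± 0.12 in naive, 8.99 ± 0.13 in memory, 8.69 ± 0.20 in PD-1int and 7.93 ± 0.12 in PD-1hi. Pdcd1, which encodes PD-1, lay at 6.80 ± 0.30, 7.10 ± 0.10, 10.12 ± 0.31 and 11.40 ± 0.15 in the same order. Against naive, Cd44 rose in memory by 2.92 ± 0.10, while Il7r (-0.40 ± 0.20) and Pdcd1 (0.31 ± 0.15) did not pass there (limma adjusted p = 0.256 and 0.241). In a fit of the 8 naive and memory arrays alone the small Il7r difference did pass, with an adjusted p of 0.00731. These genes check the sort and are not findings of their own. Pdcd1 and Il7r are members of the inhibitory receptor and central memory lists; a repeat without them, added after the data were seen, changed no call of these lists. The inhibitory receptors that rose against naive were then 8 of 14 in PD-1int and 9 of 14 in PD-1hi, as many adjusted over the list alone (camera adjusted p = 5.26e-05 and 1.31e-05).

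Memory cells differed from naive cells in transcripts of killer-cell receptors, cytotoxic molecules and cell-cycle genes. The largest rise was that of S100a6 (5.90 ± 0.14), a calcium-binding protein of activated cells, 59.6-fold. Next were Klre1 (5.36 ± 0.26), the inhibitors of cathepsin-type proteases Ctla2b (4.98 ± 0.14) and Ctla2a (4.84 ± 0.12), Samd3 (4.78 ± 0.24), Xcl1 (4.77 ± 0.24), a chemokine that attracts cross-presenting dendritic cells, and Gzmm (4.58 ± 0.12), a granzyme. Klrc3 (4.49 ± 0.43), Slamf7 (4.20 ± 0.12) and Klra6 (4.16 ± 0.23) completed the 10 largest rises; Klre1, Klrc3 and Klra6 are killer lectin-like receptors best known from natural killer cells. The largest fall was that of Itgae (-3.63 ± 0.10), the CD103 integrin chain that binds E-cadherin. Iigp1 (-3.21 ± 0.26), an interferon-inducible GTPase, Ifngr2 (-2.81 ± 0.16), a chain of the interferon gamma receptor, Gpr34 (-3.08 ± 0.14), a lysophospholipid receptor, Slc6a19 (-3.02 ± 0.11), an amino acid transporter and Slc28a2b (-3.01 ± 0.22) also fell. So did Mtss1 (-2.96 ± 0.16), Gria3 (-2.83 ± 0.10), a glutamate receptor subunit, Xkrx (-2.71 ± 0.20) and Abca3 (-2.52 ± 0.12). In all, 1487 genes were higher and 1114 lower in memory, and with quantile normalization 1387 and 1344.

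Among the killer lectin-like receptors, 12 of 14 rose (12 adjusted over the list alone, camera adjusted p = 5.76e-22), with Klrk1 (3.82 ± 0.21) and Klra9 (3.89 ± 0.25) besides those above. Of the cytotoxic effector molecules, 12 of 19 rose (15 adjusted over the list alone, camera adjusted p = 1.49e-19). Fasl (3.82 ± 0.08), the death ligand, Gzmb (3.26 ± 0.17), granzyme B, and Nkg7 (0.87 ± 0.07), a cytotoxic granule protein, had the smallest adjusted p, with Gzmm. In the effector list 14 of 19 rose (14 adjusted over the list alone, camera adjusted p = 1.30e-21), among them Anxa2 (2.50 ± 0.10), Lgals1 (2.96 ± 0.14), which encodes a galectin, and Tbx21 (2.98 ± 0.13), which encodes the transcription factor T-bet. Of the central memory genes, 8 of 13 rose and 1 fell (9 and 1 adjusted over the list alone, camera adjusted p = 4.53e-13). Eomes (2.21 ± 0.09), a T-box transcription factor, and Il2rb (1.98 ± 0.08), a receptor chain for interleukins 2 and 15, rose, and the member that fell was Ccr7 (-1.10 ± 0.15), the lymph node homing receptor. Of the naive and quiescence genes, 1 of 19 rose and 11 fell (2 and 13 adjusted over the list alone, camera adjusted p = 3.18e-10). Igfbp4 (-2.48 ± 0.13), Ccr9 (-1.61 ± 0.10), a gut-homing receptor, Lef1 (-1.09 ± 0.09), a transcription factor of naive cells, and Dapl1 (-1.13 ± 0.10) fell, and Myb (0.97 ± 0.15) was the member that rose.

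Proliferation genes were higher in memory than in naive cells. For mitosis, 30 of 34 rose (32 adjusted over the list alone, camera adjusted p = 1.15e-26, adjusted p = 0.0558 with an estimated correlation), with Mki67 (3.09 ± 0.24), Kif11 (2.47 ± 0.25), Ccna2 (2.82 ± 0.31) and Top2a (2.16 ± 0.24) at the front. For DNA replication, 30 of 37 rose (35 adjusted over the list alone, camera adjusted p = 1.65e-26, 0.0444 with an estimated correlation), including Uhrf1 (1.75 ± 0.17) and Dtl (1.95 ± 0.23). The mean of the mitosis genes, each centred on its mean over the 16 arrays, differed between memory arrays: 0.17, -0.89, -0.95 and 0.00 for replicates 1 to 4, against a mean of -1.74 ± 0.08 (SD) in naive.

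Further lists passed. Exhaustion-associated transcription factors form a set known from chronically stimulated T cells: 5 of 17 rose and 2 fell (10 and 2 adjusted over the list alone, camera adjusted p = 5.84e-05). Eomes (2.21 ± 0.09), Bhlhe40 (1.29 ± 0.13), Ikzf2 (1.14 ± 0.20), Prdm1 (1.02 ± 0.24) and Nr4a2 (0.60 ± 0.17) rose, and Irf4 (-0.79 ± 0.18) and Tox (-0.37 ± 0.10) fell. Among chemokines 3 of 13 rose (3 adjusted over the list alone, camera adjusted p = 0.00397, and adjusted p = 0.169 on ranks): Ccl5 (4.02 ± 0.08), Xcl1 (4.77 ± 0.24) and Ccl3 (1.21 ± 0.27). For glycolysis 8 of 19 rose and 2 fell (9 and 2 adjusted over the list alone, camera adjusted p = 5.35e-05), with Pfkp (0.84 ± 0.08), a phosphofructokinase, and Slc2a1 (0.64 ± 0.08), a glucose transporter. Pdk1 (-0.73 ± 0.10), which holds back pyruvate oxidation, and Hif1a (-0.37 ± 0.09) fell, Hif1a not so with the mean of its probe sets (-0.27 ± 0.09, adjusted p = 0.0558). Heat shock and unfolded protein response genes, Sdf2l1 (1.37 ± 0.12) first, shifted up as well: 7 of 21 rose (8 adjusted over the list alone, camera adjusted p = 4.55e-04). Leaving out 1 array at a time ended these calls, given with the number of 8 fits that lost each, the array whose omission gave the highest p, and that limma adjusted p: Nr4a2 (5; memory replicate 4, 0.0927) and Tox (4; memory replicate 3, 0.0838).

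Several calls were lost with an estimated correlation between genes. Of the interferon-stimulated genes, 3 of 29 rose and 12 fell (3 and 13 adjusted over the list alone, camera adjusted p = 2.93e-04, adjusted p = 0.216 with an estimated correlation). Oas3 (0.77 ± 0.14), Mx1 (0.63 ± 0.15) and Rsad2 (0.38 ± 0.10) rose. Of the cytokine receptors, 10 of 24 rose and 6 fell (14 and 6 adjusted over the list alone, camera adjusted p = 0.00567, adjusted p = 0.13 with an estimated correlation). Of the oxidative phosphorylation genes, 8 of 27 rose (9 adjusted over the list alone, camera adjusted p = 7.52e-07, adjusted p = 0.068 with an estimated correlation). Of the apoptosis regulators, 5 of 17 rose and 4 fell (7 and 4 adjusted over the list alone, camera adjusted p = 0.00847, adjusted p = 0.0558 with an estimated correlation). Fasl (3.82 ± 0.08), Bcl2l1 (1.50 ± 0.15), Casp1 (0.92 ± 0.16), Bbc3 (0.38 ± 0.10) and Pmaip1 (0.43 ± 0.13) rose, and Fas (adjusted p = 0.00153), Birc3 (-0.41 ± 0.10), Mcl1 (-0.31 ± 0.08) and Cflar (-0.40 ± 0.12) fell. Cholesterol synthesis genes shifted down (camera adjusted p = 0.0374, adjusted p = 0.315 with an estimated correlation), a call lost without naive replicate 1 (adjusted p = 0.0694), naive replicate 4 (0.203) or memory replicate 3 (0.227) as well (camera). Rsad2 (2; naive replicate 3, 0.0746), Bbc3 (4; memory replicate 4, 0.0741), Pmaip1 (6; memory replicate 4, 0.138), Mcl1 (2; memory replicate 1, 0.0776) and Cflar (6; memory replicate 1, 0.113) lost their calls when 1 array was left out.

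Few markers of other cells changed between memory and naive. Of the B-cell and CLL-cell markers, 1 of 20 rose and 1 fell (1 and 1 adjusted over the list alone, camera adjusted p = 0.984): Cd22 (3.22 ± 0.12), an inhibitory lectin of B cells, rose and Ralgps2 (-0.61 ± 0.13) fell, while Cd79a (-0.20 ± 0.19) and Ms4a1 (-0.03 ± 0.17), which encodes CD20, did not pass. Among myeloid and dendritic-cell markers 1 of 23 rose (1 adjusted over the list alone, camera adjusted p = 0.984), namely Cst3 (0.42 ± 0.07), cystatin C, and Lyz2 (-0.04 ± 0.19) did not pass. With the mean of its probe sets in place of the brightest, Cst3 did not pass (0.11 ± 0.11, adjusted p = 0.674). Of the CD4 and regulatory T-cell markers, 1 of 11 rose and 2 fell (1 and 3 adjusted over the list alone, camera adjusted p = 0.0887): Zbtb7b (0.29 ± 0.09) rose, and St8sia6 (-0.58 ± 0.11) and Ikzf4 (-0.75 ± 0.14) fell. In the list of natural killer, gamma-delta and innate-like T-cell markers 2 of 10 rose (2 adjusted over the list alone, camera adjusted p = 0.101): Klrb1c (1.33 ± 0.19) and Cd160 (1.12 ± 0.16). That list passed without memory replicate 2 (camera adjusted p = 0.0442). Cd8a did not pass (limma adjusted p = 0.994). Zbtb7b (5; naive replicate 3, 0.135) lost its call when 1 array was left out.

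PD-1int cells carried more transcripts of cytotoxic and cell-cycle genes than naive cells. Granzyme B gave the largest rise, 6.91 ± 0.17 for Gzmb or 119.9-fold (limma adjusted p = 2.53e-15). Gzma (5.68 ± 0.21) and Gzmk (5.46 ± 0.19), further granzymes, Fasl (5.24 ± 0.08) and Ccl3 (5.50 ± 0.27), a chemokine that attracts lymphocytes and macrophages, were among the 10 largest rises. The others were S100a6 (6.44 ± 0.14), Tigit (5.86 ± 0.11), an inhibitory receptor that binds CD155, Klre1 (5.76 ± 0.26), Zdhhc2 (5.56 ± 0.23), a palmitoyltransferase, and Lilrb4a (5.25 ± 0.16), a receptor with inhibitory motifs. Falls were led by Il7r (-5.47 ± 0.20), Slc28a2b (-4.88 ± 0.22), Dapl1 (-4.63 ± 0.10), Itgae (-4.37 ± 0.10), Il6ra (-4.20 ± 0.08), the interleukin 6 receptor, and Actn1 (-4.01 ± 0.15), an actin crosslinker. Ccr7 (-3.81 ± 0.15), St6gal1 (-3.75 ± 0.16), a sialyltransferase, Iigp1 (-3.70 ± 0.26) and Slc6a19 (-3.33 ± 0.11) followed. Of the genes changed, 2639 were higher and 2398 lower in PD-1int, and with quantile normalization 2425 and 2751.

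Inhibitory receptors and the transcription factors tied to exhaustion shifted up together. Of the inhibitory receptors, 9 of 15 rose and 4 fell (9 and 4 adjusted over the list alone, camera adjusted p = 2.33e-06). Besides Tigit the rises included Havcr2 (3.88 ± 0.19), which encodes TIM-3, Pdcd1 (3.32 ± 0.15) and Entpd1 (3.19 ± 0.14), an ectoenzyme that degrades ATP. Nt5e (-2.40 ± 0.19), the ectoenzyme CD73 that acts after Entpd1, fell, as did Cd274 (-1.25 ± 0.21), which encodes the PD-1 ligand PD-L1, Btla (-0.83 ± 0.13) and Vsir (-0.49 ± 0.10). Among exhaustion-associated transcription factors 16 of 17 rose and 1 fell (16 and 1 adjusted over the list alone, camera adjusted p = 4.17e-18). Maf (4.13 ± 0.20), Bhlhe40 (3.17 ± 0.13), Eomes (3.15 ± 0.09) and Nr4a2 (2.94 ± 0.17), an orphan nuclear receptor induced by T-cell receptor signals, had the smallest adjusted p, and Rbpj (-0.50 ± 0.14), the effector of Notch signals, was the exception. For naive and quiescence genes 1 of 19 rose and 17 fell (1 and 18 adjusted over the list alone, camera adjusted p = 4.20e-21), with Lef1 (-2.21 ± 0.09) among the falls and Myb (0.77 ± 0.15) again as the rise. The progenitor-exhausted list was divided: 4 of 13 rose and 4 fell (4 and 5 adjusted over the list alone, camera adjusted p = 0.184). Cxcr5 (2.16 ± 0.15) and Xcl1 (3.42 ± 0.24) rose, as did Cd28 (0.55 ± 0.13) and Bcl6 (0.35 ± 0.12), while Tnfsf8 (-3.11 ± 0.13), a TNF family ligand, Slamf6 (-1.02 ± 0.08), Lef1 and Ccr7 fell. Bcl6 did not pass with the mean of its probe sets (0.35 ± 0.12, adjusted p = 0.0501). Bcl6 (5; PD-1int replicate 2, 0.16) lost its call when 1 array was left out.

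Transcripts of effector genes were higher in PD-1int than in naive. Of the cytotoxic effector molecules, 15 of 19 rose (15 adjusted over the list alone, camera adjusted p = 2.44e-19). In the effector list 15 of 19 rose (15 adjusted over the list alone, with 1 down, camera adjusted p = 3.33e-21), with Anxa2 (3.76 ± 0.10) and Rap1gap2 (3.16 ± 0.10) besides S100a6 and Gzma. Of the killer lectin-like receptors, 10 of 14 rose and 2 fell (10 and 2 adjusted over the list alone, camera adjusted p = 7.61e-09). Klrk1 (5.05 ± 0.21), which encodes NKG2D, Klrg1 (4.61 ± 0.22), a marker of terminal effectors, and Klrc1 (3.00 ± 0.20) rose, and the falls were Klrd1 (-0.43 ± 0.14) and Klri2 (-0.36 ± 0.09). In the central memory list 6 of 13 rose and 2 fell (6 and 3 adjusted over the list alone, camera adjusted p = 0.0142, and adjusted p = 0.379 on ranks, and adjusted p = 0.0617 without the 40% dimmest genes). Slamf7 (5.16 ± 0.12) and Eomes were among the rises, and Il7r and Ccr7 fell. For chemokines 5 of 13 rose (5 adjusted over the list alone, camera adjusted p = 1.79e-04), with Ccl5 (4.39 ± 0.08), Xcl1, Ccl4 (2.73 ± 0.21) and Ccl6 (1.20 ± 0.21) besides Ccl3. Klrd1 (6; naive replicate 3, 0.116) lost its call when 1 array was left out.

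Cell-cycle genes rose without exception in the lists tested. All 34 mitosis genes rose, also over the list alone (camera adjusted p = 7.83e-35, 0.0303 with an estimated correlation). So did all 37 DNA replication genes (6.86e-31 and 0.026). Mki67 (4.57 ± 0.24), the proliferation marker Ki-67, Kif11 (3.83 ± 0.25), Ccna2 (4.37 ± 0.31), Cdk1 (3.37 ± 0.25), Uhrf1 (2.48 ± 0.17) and Tk1 (2.39 ± 0.18) were among them. Of the glycolysis genes, 10 of 19 rose and 2 fell (11 and 3 adjusted over the list alone, camera adjusted p = 9.27e-04). Gapdh (0.79 ± 0.07), Pfkp (0.93 ± 0.08) and Slc2a3 (0.87 ± 0.09), a glucose transporter, were among the rises, and Pdk1 (-2.15 ± 0.10) and Slc16a1 (-0.77 ± 0.14), a monocarboxylate transporter, were the falls. Ribosomal protein genes went down, Rps19 (-0.63 ± 0.09) and Rpl13 (-0.48 ± 0.07) first: 16 of 22 fell (17 adjusted over the list alone, camera adjusted p = 9.14e-07). Of the apoptosis regulators, 7 of 17 rose and 2 fell (8 and 4 adjusted over the list alone, camera adjusted p = 0.00148, and adjusted p = 0.164 on ranks). Casp1 (3.37 ± 0.16) and Casp4 (2.75 ± 0.16), inflammatory caspases, and Pmaip1 (1.47 ± 0.13) were up and Bbc3 (-0.82 ± 0.10) and Cflar (-0.35 ± 0.12) down. Of the heat shock and unfolded protein response genes, 9 of 21 rose and 2 fell (10 and 2 adjusted over the list alone, camera adjusted p = 0.00164), with Sdf2l1 (1.86 ± 0.12), Hsp90b1 (0.68 ± 0.06) and Xbp1 (0.72 ± 0.10) among the rises. Hspe1 (-0.44 ± 0.10) and Herpud1 (-0.38 ± 0.10) fell. Cflar (5; naive replicate 1, 0.121) lost its call when 1 array was left out.

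Other calls were lost with an estimated correlation. Of the early genes that T-cell receptor signals induce, 14 of 27 rose and 5 fell (14 and 5 adjusted over the list alone, camera adjusted p = 3.72e-04, adjusted p = 0.109 with an estimated correlation). Ppp1r15a (-0.74 ± 0.14), Myc (-0.91 ± 0.19), Nfkbia (-0.34 ± 0.08), Jun (-1.12 ± 0.26) and Cd69 (-0.41 ± 0.13) fell. Of the interferon-stimulated genes, 5 of 29 rose and 12 fell (5 and 12 adjusted over the list alone, camera adjusted p = 0.0147, adjusted p = 0.395 with an estimated correlation). Mx1 (1.10 ± 0.15), Gbp3 (0.69 ± 0.15), Rsad2 (0.41 ± 0.10), Isg15 (0.44 ± 0.12) and Dhx58 (0.42 ± 0.13) rose. Of the oxidative phosphorylation genes, 8 of 27 rose and 1 fell (8 and 1 adjusted over the list alone, camera adjusted p = 0.00868, adjusted p = 0.312 with an estimated correlation). Sdha (-0.35 ± 0.07) fell. Cd69 (5; naive replicate 1, 0.12) and Dhx58 (5; naive replicate 2, 0.113) lost their calls when 1 array was left out.

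Some markers of other cells moved with these groups. Among B-cell and CLL-cell markers 1 of 20 rose and 5 fell (1 and 5 adjusted over the list alone, camera adjusted p = 0.354). Ighm (-2.98 ± 0.26), the immunoglobulin heavy chain of IgM, Cd79b (-0.72 ± 0.13), Bank1 (-0.83 ± 0.19), Pou2af1 (-0.38 ± 0.10) and Ralgps2 (-0.81 ± 0.13) fell, and Cd22 (1.75 ± 0.12) rose. With the mean of its 7 probe sets Ighm changed less (-0.74 ± 0.10, adjusted p = 1.46e-05), as in PD-1hi against naive (-0.85 ± 0.10) and PD-1int and PD-1hi against memory (-0.68 and -0.79, each ± 0.10). Cd79a (-0.08 ± 0.19) and Ms4a1 (0.19 ± 0.17) did not pass. Of the myeloid and dendritic-cell markers, 3 of 23 rose and 1 fell (3 and 1 adjusted over the list alone, camera adjusted p = 0.0339, adjusted p = 0.127 with an estimated correlation). Cd68 (2.86 ± 0.17), a lysosomal glycoprotein, Hmox1 (1.08 ± 0.11) and Cst3 (0.49 ± 0.07) rose and Cd209a (-0.37 ± 0.10) fell, while Lyz2 (0.27 ± 0.19), Csf1r (0.05 ± 0.14) and S100a8 (0.15 ± 0.14) did not pass. With the mean of its probe sets Cst3 did not pass (0.27 ± 0.11, adjusted p = 0.0984). The myeloid list did not pass without naive replicate 1 (adjusted p = 0.0603) or without PD-1int replicate 2 (adjusted p = 0.0735) (camera). Of the CD4 T-cell and regulatory T-cell markers, 3 of 11 rose and 2 fell (3 and 2 adjusted over the list alone, camera adjusted p = 0.73). Ctla4 (1.90 ± 0.13), Rora (0.74 ± 0.11) and Zbtb7b (0.26 ± 0.09) rose while Ikzf4 (-0.56 ± 0.14) and St8sia6 (-0.53 ± 0.11) fell, and Cd4 (0.07 ± 0.11) and Foxp3 (-0.16 ± 0.10) did not pass. Cd8b1 (-0.32 ± 0.07) fell slightly and Cd8a (-0.23 ± 0.10) did not pass, though it did without PD-1int replicate 2 (limma adjusted p = 0.0178). Cd209a (1; PD-1int replicate 4, 0.0593) and Zbtb7b (5; naive replicate 3, 0.127) lost their calls when 1 array was left out.

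PD-1hi cells stood farthest from naive cells, with 2981 genes higher and 3039 lower (2815 and 3375 with quantile normalization). Il7r had the largest change of all, -8.05 ± 0.20 or 266-fold lower (limma adjusted p = 2.29e-15). Gzmb (128-fold, with a log2 standard error of 0.17), Tigit (6.66 ± 0.11), Ccl3 (6.65 ± 0.27), S100a6 (6.54 ± 0.14) and Zdhhc2 (5.68 ± 0.23) led the rises, followed by Car5b (5.59 ± 0.16), a mitochondrial carbonic anhydrase, Lilrb4a (5.54 ± 0.16), Gzmk (5.52 ± 0.19), Fasl (5.44 ± 0.08) and Klre1 (5.37 ± 0.26). After Il7r the largest falls were those of Dapl1 (-5.10 ± 0.10), Cd226 (-5.05 ± 0.57), an activating receptor that competes with TIGIT for CD155, Slc28a2b (-5.00 ± 0.22) and Treml2 (-4.75 ± 0.18). Il6ra (-4.60 ± 0.08), Itgae (-4.33 ± 0.10), Nt5e (-4.21 ± 0.19), Ssbp2 (-4.15 ± 0.29) and Ccr7 (-4.09 ± 0.15) completed the 10. Cd226 had the largest standard error of these, and its PD-1hi arrays ranged from 4.72 in replicate 1 to 8.20 in replicate 2.

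Of the inhibitory receptors, 10 of 15 rose and 4 fell (10 and 4 adjusted over the list alone, camera adjusted p = 5.46e-07). Havcr2 (5.17 ± 0.19), Pdcd1 (4.61 ± 0.15) and Entpd1 (3.87 ± 0.14) rose besides Tigit, and the falls were again Nt5e, Cd274 (-1.53 ± 0.21), Vsir (-0.70 ± 0.10) and Btla (-0.57 ± 0.13). Of the exhaustion-associated transcription factors, 16 of 17 rose and 1 fell (16 and 1 adjusted over the list alone, camera adjusted p = 4.52e-18), with Maf (5.06 ± 0.20), Nr4a2 (4.67 ± 0.17), Bhlhe40 (3.65 ± 0.13) and Eomes (3.26 ± 0.09) in front and Rbpj (-0.46 ± 0.14) as the exception. Of the naive and quiescence genes, 1 of 19 rose and 18 fell (1 and 18 adjusted over the list alone, camera adjusted p = 1.97e-21), with Lef1 (-3.05 ± 0.09) among the falls and Myb (0.58 ± 0.15) as the rise. For progenitor-exhausted genes 3 of 13 rose and 6 fell (4 and 6 adjusted over the list alone, camera adjusted p = 0.0306, adjusted p = 0.193 with an estimated correlation). Cxcr5 (2.09 ± 0.15), Xcl1 (2.35 ± 0.24) and Cd28 (0.38 ± 0.13) rose. Rbpj (2; naive replicate 4, 0.0614) and Cd28 (5; naive replicate 4, 0.12) lost their calls when 1 array was left out.

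Cytotoxic genes were high but not uniformly so. Of the cytotoxic effector molecules, 12 of 19 rose and 2 fell (13 and 2 adjusted over the list alone, camera adjusted p = 1.34e-11). Gzma (5.26 ± 0.21) rose, and Tnf (-0.74 ± 0.13), which encodes a secreted cytokine, and Lamp1 (-0.55 ± 0.14), a lysosomal membrane protein, fell. In the effector list 14 of 19 rose and 3 fell (14 and 3 adjusted over the list alone, camera adjusted p = 1.06e-11). Anxa2 (3.83 ± 0.10), Lgals1 (3.74 ± 0.14) and Rap1gap2 (2.71 ± 0.10) rose, whereas Ly6c2 (-2.48 ± 0.32), Ly6c1 (-0.73 ± 0.18) and Klf6 (-0.82 ± 0.10) fell. For killer lectin-like receptors 9 of 14 rose and 1 fell (9 and 2 adjusted over the list alone, camera adjusted p = 3.08e-05), with Klrk1 (4.27 ± 0.21), Klrg1 (3.71 ± 0.22) and Klrc1 (2.23 ± 0.20) up and Klrd1 (-0.75 ± 0.14) down. The central memory list did not pass (camera adjusted p = 0.941). For chemokines 6 of 13 rose (6 adjusted over the list alone, camera adjusted p = 1.46e-05). Csf1 (2.95 ± 0.23), the growth factor of macrophages, joined Ccl5 (4.46 ± 0.08), Ccl4 (3.51 ± 0.21), Ccl6 (1.57 ± 0.21) and Xcl1.

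All 34 mitosis genes rose, also over the list alone (camera adjusted p = 3.71e-37, 0.0308 with an estimated correlation). So did all 37 DNA replication genes (2.19e-31 and 0.0308). Mki67 (5.22 ± 0.24), Kif11 (4.74 ± 0.25), Prc1 (3.80 ± 0.21), Top2a (4.05 ± 0.24), Uhrf1 (2.84 ± 0.17) and Chaf1a (2.19 ± 0.13) were among the rises. Ribosomal protein genes went down, with Rpl13 (-0.71 ± 0.07) and Rps19 (-0.82 ± 0.09) first: 17 of 22 fell (18 adjusted over the list alone, camera adjusted p = 8.61e-10). For glycolysis 11 of 19 rose and 2 fell (11 and 2 adjusted over the list alone, camera adjusted p = 0.00209), with Slc2a3 (1.18 ± 0.09) and Gapdh (0.89 ± 0.07) up and Pdk1 (-2.83 ± 0.10) and Slc16a1 (-1.30 ± 0.14) down. Interferon-stimulated genes, which type I and type II interferons induce, were lower: 1 of 29 rose and 17 fell (2 and 18 adjusted over the list alone, camera adjusted p = 4.72e-09, adjusted p = 0.0586 with an estimated correlation). Igtp (-2.86 ± 0.16), Irgm1 (-1.81 ± 0.10), Usp18 (-2.04 ± 0.12) and Iigp1 (-4.00 ± 0.26) fell and Gbp3 (0.44 ± 0.15) rose. Further calls were lost with an estimated correlation. Of the early genes that T-cell receptor signals induce, 12 of 27 rose and 4 fell (13 and 4 adjusted over the list alone, camera adjusted p = 0.00176, adjusted p = 0.177 with an estimated correlation). Myc (-1.56 ± 0.19), Ppp1r15a (-1.05 ± 0.14), Cd69 (-0.85 ± 0.13) and Jun (-1.49 ± 0.26) fell. Of the oxidative phosphorylation genes, 8 of 27 rose and 1 fell (9 and 1 adjusted over the list alone, camera adjusted p = 0.00624, adjusted p = 0.298 with an estimated correlation). Sdha (-0.42 ± 0.07) fell. Of the apoptosis regulators, 7 of 17 rose and 4 fell (8 and 4 adjusted over the list alone, camera adjusted p = 0.0158, adjusted p = 0.0672 with an estimated correlation). Bbc3 (-0.84 ± 0.10), Fas (-0.92 ± 0.19), Cflar (-0.47 ± 0.12) and Bcl2 (-0.53 ± 0.15) fell. In the heat shock and unfolded protein response list 9 of 21 rose and 2 fell (9 and 4 adjusted over the list alone, camera adjusted p = 0.0352, adjusted p = 0.18 with an estimated correlation). Hspe1 (-0.42 ± 0.10) and Hspa1a (-0.82 ± 0.26) fell. That call was also lost without naive replicate 2 (adjusted p = 0.051), naive replicate 3 (0.0516) or PD-1hi replicate 1 (0.0511), again with camera. Gbp3 (5; naive replicate 1, 0.158) and Hspa1a (2; naive replicate 2, 0.0761) lost their calls when 1 array was left out.

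Beside these groups, markers of other cells moved in small numbers. Of the B-cell and CLL-cell markers, 1 of 20 rose and 4 fell (1 and 4 adjusted over the list alone, camera adjusted p = 0.282): Ighm (-3.68 ± 0.26), Cd79b (-0.97 ± 0.13), Bank1 (-0.91 ± 0.19) and Ralgps2 (-0.97 ± 0.13) fell and Cd22 (0.84 ± 0.12) rose. Cd79a (-0.17 ± 0.19), Ms4a1 (0.05 ± 0.17) and Pax5 (0.11 ± 0.09) did not pass. Of the myeloid and dendritic-cell markers, 3 of 23 rose and 2 fell (3 and 2 adjusted over the list alone, camera adjusted p = 0.253). Cd68 (3.05 ± 0.17), Hmox1 (0.89 ± 0.11) and Cst3 (0.57 ± 0.07) rose and Cd209a (-0.47 ± 0.10) and Ms4a6c (-0.65 ± 0.18) fell. Lyz2 (0.50 ± 0.19, limma adjusted p = 0.0574) and Csf1r (0.25 ± 0.14) did not pass. Lyz2 did pass in a fit of the 8 arrays alone (adjusted p = 0.028), with quantile normalization (0.0409) or median centring (0.0496), and without naive replicate 1 (0.0449) or PD-1hi replicate 3 (0.0425) (limma), so a small rise of this myeloid transcript stays open. Among erythroid and platelet markers 1 of 9 rose (1 adjusted over the list alone, camera adjusted p = 0.658), namely Ppbp (1.06 ± 0.26), a platelet chemokine. Of the CD4 and regulatory T-cell markers, 3 of 11 rose and 1 fell (3 and 1 adjusted over the list alone, camera adjusted p = 0.382). Ctla4 (2.86 ± 0.13), Rora (0.49 ± 0.11) and Zbtb7b (0.28 ± 0.09) rose, and St8sia6 (-0.55 ± 0.11) fell. Foxp3 (-0.22 ± 0.10) did not pass. Of the natural killer, gamma-delta and innate-like markers, 2 of 10 rose (2 adjusted over the list alone, camera adjusted p = 0.11). Maf (5.06 ± 0.20) and Cd160 (1.22 ± 0.16) rose. Zbtb7b (5; naive replicate 3, 0.0865) lost its call when 1 array was left out.

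**Figure D3:**
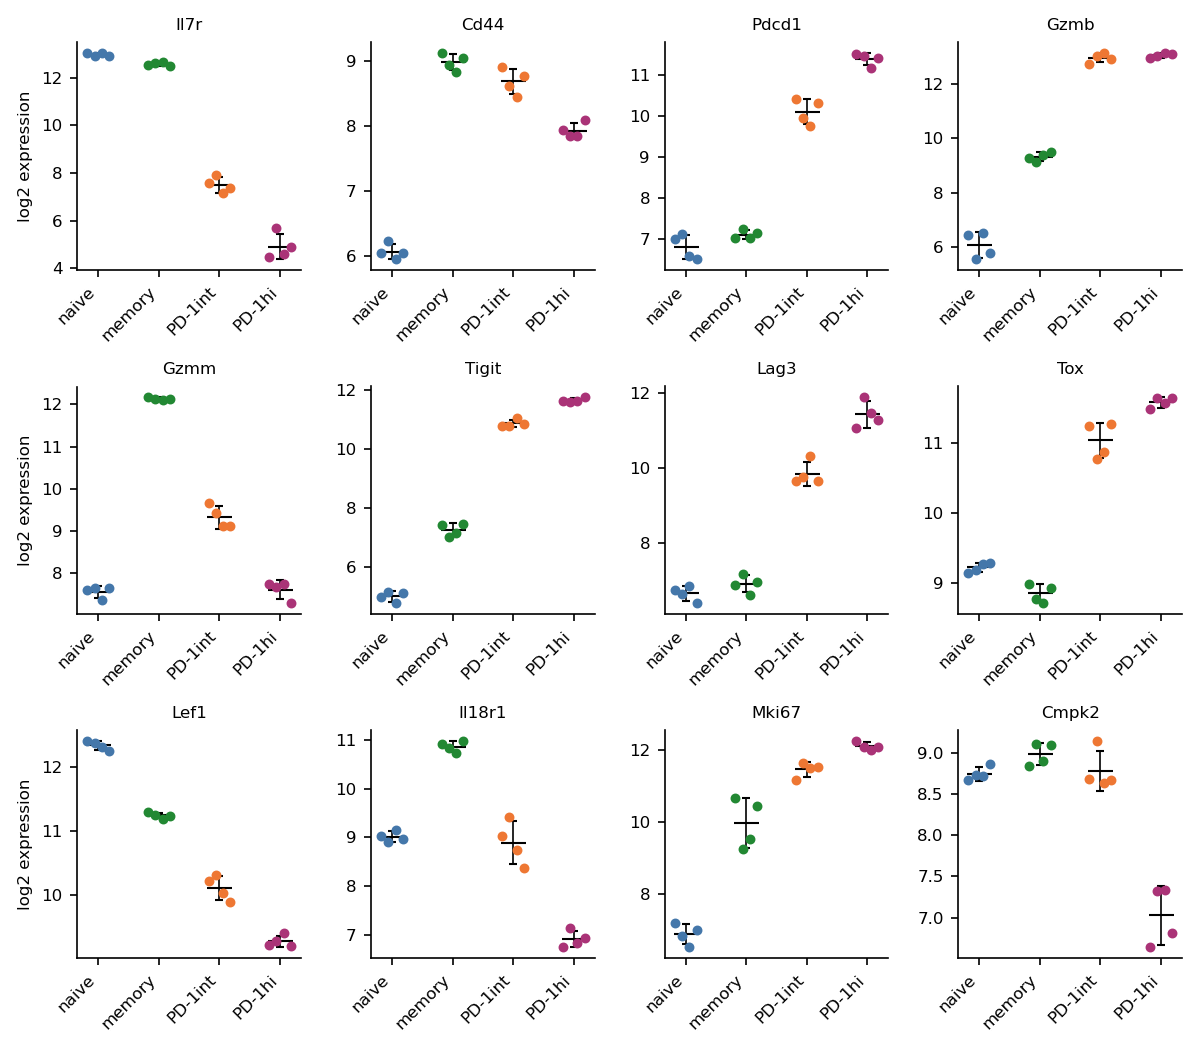
Log2 expression of 12 genes on each of the 16 arrays (y axis), by subset (x axis), with each point 1 array and the bar the mean of 4 with its SD. Il7r fell from a mean of 12.97 in naive to 4.91 in PD-1hi, Gzmb rose from 6.07 to 13.08, and Gzmm was highest in memory at 12.13.

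Between the effector subsets, PD-1hi cells carried more transcripts of inhibitory receptors and exhaustion-associated transcription factors and fewer of effector, central memory and interferon-stimulated genes than PD-1int cells. The largest rise was that of Adgrg1 (2.79 ± 0.17), an adhesion receptor (GPR56) of cytotoxic lymphocytes, 6.92-fold. Csf1 (2.68 ± 0.23), Coch (2.39 ± 0.42), Arnt2 (2.00 ± 0.17), a basic helix-loop-helix transcription factor, Nr4a2 (1.73 ± 0.17) and Chn2 (1.64 ± 0.17), a GTPase-activating protein for Rac, followed. Lag3 (1.57 ± 0.17), an inhibitory receptor that binds MHC class II, Glp1r (1.53 ± 0.24), the receptor of an incretin hormone, Cd200r1 (1.49 ± 0.28), an inhibitory receptor, and Itih5 (1.46 ± 0.18) completed the 10 largest rises. The largest falls were those of Samd3 (-3.01 ± 0.24), Cyp17a1 (-3.01 ± 0.23), a steroid hydroxylase, Il7r (-2.58 ± 0.20), Il18rap (-2.37 ± 0.27) and Il18r1 (-1.97 ± 0.16), the chains of the interleukin 18 receptor, and Ly6c2 (-2.33 ± 0.32), a surface marker of effector and memory cells. Klhl6 (-1.95 ± 0.15), Parp8 (-1.90 ± 0.17), Slco3a1 (-1.82 ± 0.18), an organic anion transporter, and Nt5e (-1.81 ± 0.19) also fell. Pdcd1, the basis of the gate, rose by 1.29 ± 0.15, and Cd44 fell (-0.76 ± 0.10; limma adjusted p = 2.41e-04).

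Of the inhibitory receptors, 9 of 15 rose and 1 fell (10 and 1 adjusted over the list alone, camera adjusted p = 1.18e-09), with Lag3 and Ctla4 (0.97 ± 0.13) among the rises and Nt5e as the fall. Without Pdcd1, whose rise the gate fixes, 8 of 14 rose and 1 fell (9 and 1 adjusted over the list alone, camera adjusted p = 7.59e-08). Of the exhaustion-associated transcription factors, 6 of 17 rose (10 adjusted over the list alone, camera adjusted p = 1.58e-10): Tox (0.55 ± 0.10), a regulator of exhausted cells, Tox2 (0.46 ± 0.11), Batf (0.46 ± 0.09), Maf (0.93 ± 0.20) and Ikzf2 (0.92 ± 0.20) besides Nr4a2. Of the naive and quiescence genes, 1 of 19 rose and 8 fell (1 and 9 adjusted over the list alone, camera adjusted p = 2.64e-09), with Lef1 (-0.83 ± 0.09), S1pr1 (-0.90 ± 0.10), the receptor for exit from lymphoid organs, and Treml2 (-1.54 ± 0.18) down and Actn1 (0.85 ± 0.15) up. In the progenitor-exhausted list 5 of 13 fell (5 adjusted over the list alone, camera adjusted p = 1.37e-05): Bcl6 (-0.88 ± 0.12), Xcl1 (-1.06 ± 0.24), Slamf6 (-0.34 ± 0.08), Id3 (-0.55 ± 0.14) and Lef1. With the mean of its probe sets Slamf6 did not pass (-0.38 ± 0.12, adjusted p = 0.118). Of the central memory genes, 7 of 13 fell (8 adjusted over the list alone, with 1 up, camera adjusted p = 1.54e-11), Samd3, Il7r, Il18r1 and Itgb1 (-1.23 ± 0.17), an integrin chain, among them. Tox2 (5; PD-1int replicate 1, 0.1), Ikzf2 (5; PD-1hi replicate 4, 0.0583), Xcl1 (4; PD-1int replicate 1, 0.0772), Slamf6 (3; PD-1int replicate 1, 0.0901) and Id3 (6; PD-1int replicate 1, 0.112) lost their calls when 1 array was left out.

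Effector genes were lower in PD-1hi. Of the effector and short-lived effector genes, 8 of 19 fell (10 adjusted over the list alone, camera adjusted p = 1.08e-07), with Itgax (-1.63 ± 0.25), S1pr5 (-0.87 ± 0.13) and Klf6 (-0.58 ± 0.10) besides Ly6c2. Of the killer lectin-like receptors, 6 of 14 fell (6 adjusted over the list alone, camera adjusted p = 9.13e-07): Klra9 (-1.40 ± 0.25), Klrb1f (-1.34 ± 0.28), Klrg1 (-0.90 ± 0.22), Klrc1 (-0.77 ± 0.20), Klrc2 (-1.19 ± 0.32) and Klrk1 (-0.78 ± 0.21). Cytotoxic effector molecules went both ways and did not pass as a list (camera adjusted p = 0.521): 2 of 19 rose and 3 fell (2 and 4 adjusted over the list alone). Gzmm (-1.72 ± 0.12), Ctsw (-0.61 ± 0.08), a cathepsin of cytotoxic cells, and Lamp1 (-0.69 ± 0.14) fell, whereas Ifng (0.99 ± 0.20), which encodes interferon gamma, and Serpinb6b (0.69 ± 0.14), a serpin, rose. Gzmb differed by 0.10 ± 0.17 and did not pass (limma adjusted p = 0.875). Among chemokines 3 of 13 rose and 1 fell (3 and 1 adjusted over the list alone, camera adjusted p = 0.0143, adjusted p = 0.0761 with an estimated correlation). Ccl3 (1.15 ± 0.27) and Ccl4 (0.78 ± 0.21) rose with Csf1, and Xcl1 fell. Klrg1 (6; PD-1hi replicate 4, 0.103), Klrc1 (6; PD-1int replicate 2, 0.143), Klrc2 (7; PD-1hi replicate 1, 0.161), Klrk1 (6; PD-1int replicate 1, 0.111), Ccl3 (4; PD-1int replicate 1, 0.084) and Ccl4 (6; PD-1int replicate 1, 0.16) lost their calls when 1 array was left out.

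Interferon-stimulated genes were lower in PD-1hi: 14 of 29 fell (19 adjusted over the list alone, with 2 up, camera adjusted p = 3.05e-19), with Cmpk2 (-1.76 ± 0.15), Rtp4 (-0.95 ± 0.11), Usp18 (-0.99 ± 0.12) and Oas3 (-1.13 ± 0.14) first. Ifnar2 (-1.16 ± 0.10), a chain of the type I interferon receptor, fell too. Of the cytokine receptors, 1 of 24 rose and 6 fell (4 and 9 adjusted over the list alone, camera adjusted p = 5.18e-04, adjusted p = 0.0703 with an estimated correlation). Il6st (0.43 ± 0.10) rose. Mitosis genes leaned up, Kif20a (0.89 ± 0.17), Cenpf (0.87 ± 0.17), Melk (0.99 ± 0.19) and Ttk (1.10 ± 0.22) first: 12 of 34 rose (33 adjusted over the list alone, camera adjusted p = 2.51e-26, adjusted p = 0.0691 with an estimated correlation). For DNA replication 1 of 37 rose (9 adjusted over the list alone, camera adjusted p = 1.03e-11, adjusted p = 0.188 with an estimated correlation): Rrm1 (0.81 ± 0.20). Of the ribosomal protein genes, 1 of 22 fell (4 adjusted over the list alone, camera adjusted p = 2.42e-07, adjusted p = 0.0544 with an estimated correlation): Rps9 (-0.28 ± 0.07), which did not pass with the mean of its probe sets (-0.26 ± 0.10, adjusted p = 0.185). Il6st (6; PD-1int replicate 4, 0.0817), Rrm1 (5; PD-1int replicate 1, 0.0965) and Rps9 (7; PD-1int replicate 1, 0.135) lost their calls when 1 array was left out.

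Markers of other cell types differed little between the 2 effector subsets. Among B-cell and CLL-cell markers 1 of 20 fell (1 adjusted over the list alone, camera adjusted p = 0.216), namely Cd22 (-0.90 ± 0.12). Ighm differed by -0.70 ± 0.26 and did not pass. Among myeloid and dendritic-cell markers 1 of 23 fell (1 adjusted over the list alone, camera adjusted p = 0.326), namely Ms4a6c (-0.74 ± 0.18), and Cd68 (0.19 ± 0.17) did not pass. Among CD4 and regulatory T-cell markers 2 of 11 rose (2 adjusted over the list alone, camera adjusted p = 0.161): Ctla4 (0.97 ± 0.13) and Ikzf4 (0.71 ± 0.14) rose, while Foxp3 (-0.06 ± 0.10) did not pass. Ms4a6c (6; PD-1int replicate 1, 0.0965) lost its call when 1 array was left out.

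**Figure D4:**
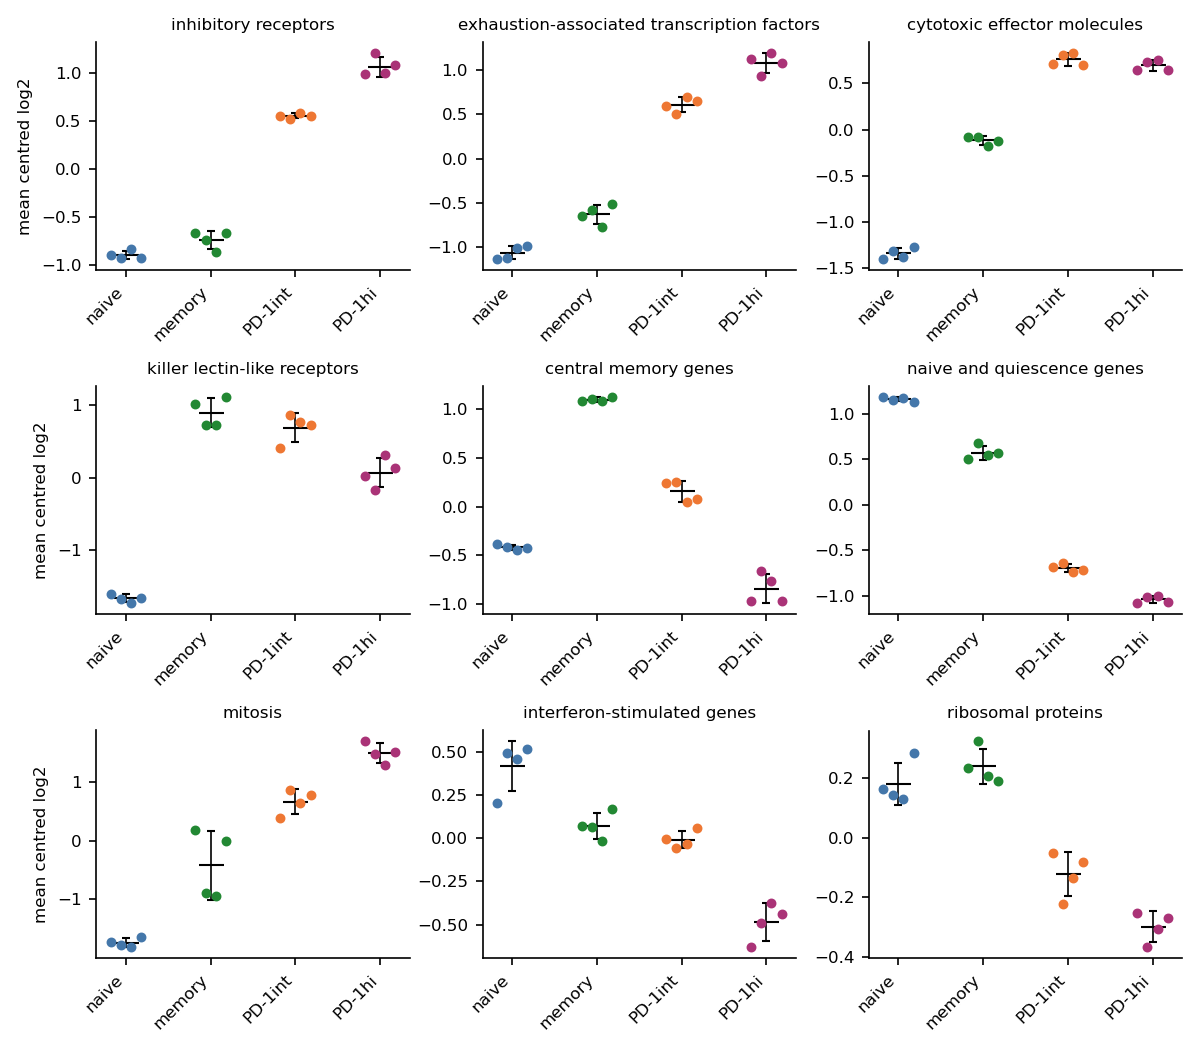
Mean of the genes of 9 lists on each array (y axis, log2 after each gene was centred on its mean over the 16 arrays), by subset (x axis); each point is 1 array and the bar the mean of 4 with its SD. The mitosis genes lay at -1.74 in naive and 1.49 in PD-1hi.

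PD-1int cells differed from memory cells in 3584 genes, 1884 higher and 1700 lower (1816 and 1817 with quantile normalization), and in 585 by at least 2-fold. Ccl3 (4.29 ± 0.27), Car5b (3.95 ± 0.16) and Havcr2 (3.93 ± 0.19) rose most, and Il7r (-5.08 ± 0.20), Il6ra (-3.79 ± 0.08) and St6gal1 (-3.71 ± 0.16) fell most. Cd44, which both gates allow to be high, differed by -0.30 ± 0.10 (limma adjusted p = 0.0525). Cd44 passed without the 40% dimmest genes (adjusted p = 0.0341), with quantile normalization (0.0213) or array weights (0.0272), and without memory replicate 3 (0.0401) or PD-1int replicate 1 (0.018) (limma). Of the inhibitory receptors, 9 of 15 rose and 2 fell (9 and 3 adjusted over the list alone, camera adjusted p = 1.17e-08). Nt5e (-2.28 ± 0.19) and Btla (-1.17 ± 0.13) fell. Of the exhaustion-associated transcription factors, 14 of 17 rose and 1 fell (15 and 1 adjusted over the list alone, camera adjusted p = 1.80e-17). Rbpj (-0.61 ± 0.14) fell. Of the cytotoxic effector molecules, 13 of 19 rose and 3 fell (13 and 3 adjusted over the list alone, camera adjusted p = 7.71e-09). Gzmm (-2.81 ± 0.12), Tnf (-0.61 ± 0.13) and Ctsw (-0.28 ± 0.08) fell. Of the central memory genes, 2 of 13 rose and 8 fell (2 and 9 adjusted over the list alone, camera adjusted p = 1.55e-04). Eomes (0.94 ± 0.09) and Slamf7 (0.96 ± 0.12) rose. Of the naive and quiescence genes, 1 of 19 rose and 15 fell (1 and 15 adjusted over the list alone, camera adjusted p = 2.41e-16). Klf3 (0.28 ± 0.08) rose. Ctsw (3; PD-1int replicate 2, 0.0633) and Klf3 (5; PD-1int replicate 1, 0.0761) lost their calls when 1 array was left out.

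Further lists were compared between PD-1int and memory. In the tissue-residency list 1 of 13 rose and 6 fell (1 and 9 adjusted over the list alone, camera adjusted p = 0.00116), Rgs1 (1.85 ± 0.22) being the rise. Of the mitosis genes, 33 of 34 rose (34 adjusted over the list alone, camera adjusted p = 6.38e-20, adjusted p = 0.107 with an estimated correlation), and of the ribosomal protein genes, 17 of 22 fell (17 adjusted over the list alone, camera adjusted p = 3.04e-11). Of the B-cell and CLL-cell markers, 4 of 20 fell (4 adjusted over the list alone, camera adjusted p = 0.0659). Cd22 (-1.47 ± 0.12), Ighm (-2.67 ± 0.26), Pou2af1 (-0.57 ± 0.10) and Cd79b (-0.57 ± 0.13) fell. This list passed without the 40% dimmest genes (adjusted p = 0.0114), with array weights (0.0483), without memory replicate 1 (0.0316), 2 (0.032) or 3 (0.0412), and without PD-1int replicate 4 (0.00982) (camera). Of the myeloid and dendritic-cell markers, 3 of 23 rose and 1 fell (3 and 1 adjusted over the list alone, camera adjusted p = 0.00553, adjusted p = 0.0645 with an estimated correlation). Cd68 (2.41 ± 0.17), Hmox1 (0.88 ± 0.11) and Ms4a6c (0.66 ± 0.18) rose, and Cd209a (-0.51 ± 0.10) fell. Ms4a6c (2; memory replicate 3, 0.0673) lost its call when 1 array was left out.

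Effector genes and apoptosis regulators shifted up in PD-1int against memory (camera adjusted p = 7.60e-09 and 0.00194). Other lists passed there with the preset correlation only, given with the camera adjusted p with the preset and with an estimated correlation: progenitor-exhausted genes (0.0171; 0.157), chemokines (0.0259; 0.11), costimulatory receptors (0.0264; 0.164), T-cell-receptor-induced early genes (1.13e-05; 0.0645), DNA replication (1.77e-13; 0.139) and cholesterol synthesis (0.00465; 0.175).

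PD-1hi cells differed from memory cells in 4868 genes, 2400 higher and 2468 lower, and in 1014 by at least 2-fold. Ccl3 (5.44 ± 0.27), Havcr2 (5.23 ± 0.19) and Maf (4.58 ± 0.20) rose most, and Il7r (-7.66 ± 0.20), Treml2 (-4.72 ± 0.18) and Trim30c (-4.54 ± 0.22) fell most. Cd44 was lower in PD-1hi than in memory (-1.06 ± 0.10; limma adjusted p = 3.38e-07). Of the inhibitory receptors, 9 of 15 rose and 2 fell (9 and 2 adjusted over the list alone, camera adjusted p = 2.77e-08). Nt5e (-4.09 ± 0.19) and Btla (-0.91 ± 0.13) fell. Of the exhaustion-associated transcription factors, 16 of 17 rose and 1 fell (16 and 1 adjusted over the list alone, camera adjusted p = 4.95e-18), with Tox (2.73 ± 0.10) and Nr4a2 (4.07 ± 0.17) among the rises and Rbpj (-0.57 ± 0.14) as the fall. Of the cytotoxic effector molecules, 12 of 19 rose and 4 fell (13 and 4 adjusted over the list alone, camera adjusted p = 5.94e-06). Gzmm (-4.53 ± 0.12), Ctsw (-0.89 ± 0.08), Tnf (-1.06 ± 0.13) and Lamp1 (-0.92 ± 0.14) fell. Of the central memory genes, 2 of 13 rose and 9 fell (2 and 9 adjusted over the list alone, camera adjusted p = 4.22e-07), Il18r1 (-3.94 ± 0.16) and Samd3 (-3.92 ± 0.24) among the falls. Eomes (1.04 ± 0.09) and Slamf7 (0.62 ± 0.12) rose.

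Further lists were compared between PD-1hi and memory. Of the naive and quiescence genes, 15 of 19 fell (17 adjusted over the list alone, with 1 up, camera adjusted p = 1.95e-18). Of the mitosis genes, 34 of 34 rose (34 adjusted over the list alone, camera adjusted p = 2.20e-29, adjusted p = 0.0584 with an estimated correlation). Of the interferon-stimulated genes, 5 of 29 rose and 17 fell (5 and 18 adjusted over the list alone, camera adjusted p = 2.35e-06, adjusted p = 0.0926 with an estimated correlation). Isg20 (0.45 ± 0.09), Zbp1 (0.54 ± 0.11), Gbp3 (0.67 ± 0.15), Parp14 (0.33 ± 0.09) and Isg15 (0.40 ± 0.12) rose. Of the ribosomal protein genes, 17 of 22 fell (19 adjusted over the list alone, camera adjusted p = 4.45e-14). Of the B-cell and CLL-cell markers, 4 of 20 fell (4 adjusted over the list alone, camera adjusted p = 0.0435, adjusted p = 0.321 with an estimated correlation). Cd22 (-2.37 ± 0.12), Ighm (-3.37 ± 0.26), Cd79b (-0.82 ± 0.13) and Pou2af1 (-0.40 ± 0.10) fell. Without memory replicate 4 that list did not pass (adjusted p = 0.209; camera), as was the case without PD-1hi replicate 2 (0.0537) or replicate 3 (0.0548). Of the CD4 and regulatory T-cell markers, 3 of 11 rose (3 adjusted over the list alone, camera adjusted p = 0.0481, adjusted p = 0.0926 with an estimated correlation): Ctla4 (3.13 ± 0.13), Rora (0.79 ± 0.11) and Ikzf4 (0.90 ± 0.14) rose. That list did not pass without memory replicate 1 (adjusted p = 0.0638) or 3 (0.0508), nor without PD-1hi replicate 1 (0.0549) or 3 (0.0654) (camera). Of the myeloid and dendritic-cell markers, 3 of 23 rose and 1 fell (2 and 1 adjusted over the list alone, camera adjusted p = 0.0936). Cd68 (2.60 ± 0.17), Hmox1 (0.70 ± 0.11) and Lyz2 (0.53 ± 0.19) rose, and Cd209a (-0.62 ± 0.10) fell. Isg15 (4; PD-1hi replicate 3, 0.108) and Lyz2 (6; PD-1hi replicate 2, 0.159) lost their calls when 1 array was left out.

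In PD-1hi against memory the same held, with the 2 values given in that order, for progenitor-exhausted genes (3.34e-04; 0.0584), effector and short-lived effector genes (0.0036; 0.0926), killer lectin-like receptors (0.00111; 0.0896), chemokines (0.00363; 0.0584), cytokine receptors (0.00363; 0.0926), tissue-residency genes (0.025; 0.0825), T-cell-receptor-induced early genes (3.99e-04; 0.0926), DNA replication (4.25e-19; 0.0825), cholesterol synthesis (0.0435; 0.328) and apoptosis regulators (0.0388; 0.0926). Without memory replicate 3 (adjusted p = 0.114), PD-1hi replicate 1 (0.0968) or PD-1hi replicate 3 (0.0548) the cholesterol list did not pass, nor did the apoptosis list without memory replicate 3 (0.0508) or PD-1hi replicate 3 (0.0632) (camera).

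The variable segments of the T-cell receptor differed more between arrays in the effector subsets than in naive cells. A subset made of a few large clones can vary between mice in the segments it contains. Over the 6 Trav and Trbv segments with a probe set of their own, the mean absolute deviation of an array from its subset mean was 0.159 ± 0.052 in naive, 0.115 ± 0.065 in memory, 0.306 ± 0.083 in PD-1int and 0.513 ± 0.095 in PD-1hi (log2, mean ± SD, n = 4). PD-1int exceeded naive by 0.146 and PD-1hi by 0.354. Each had an exact two-sided permutation p of 0.0286, the smallest possible (adjusted p = 0.0429 over 3 tests). The 4 deviations of a subset share its mean and are not independent, so this p can be too small. The PD-1int difference was 0.067 without replicate 3 and 0.22 without replicate 4. Memory differed from naive by -0.044 (exact permutation p = 0.343, adjusted 0.343). Trav14d-3-dv8 ran from 8.59 to 11.01 over the PD-1hi arrays and from 9.48 to 10.16 over the naive ones, and Trbv13-2 from 8.61 to 10.81 in PD-1hi. Trav9d-3 stayed within 13.48 to 13.61 in PD-1hi. On the upper segments by mean expression neither PD-1int (adjusted p = 0.600) nor PD-1hi (0.0857) passed the same exact test.

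**Figure D5:**
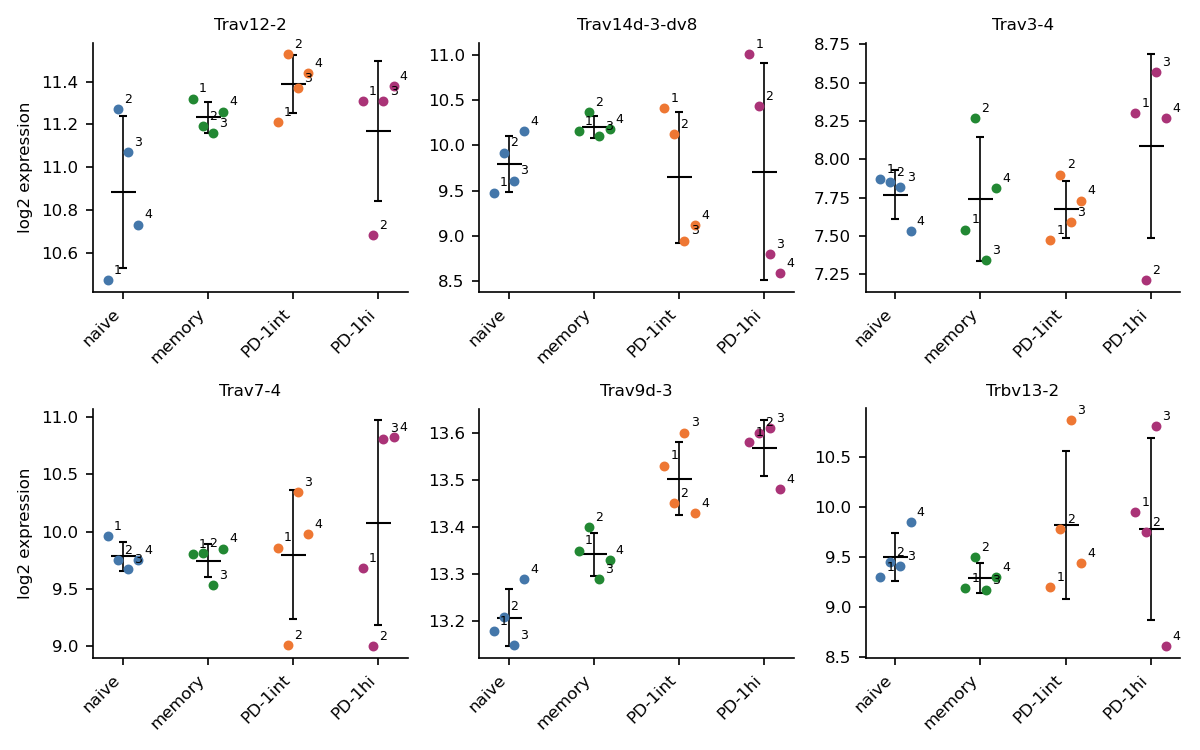
Log2 expression of the 6 T-cell receptor variable segments (one panel each) on the 16 arrays, by subset (x axis), each point 1 array marked with its replicate number. Trav14d-3-dv8, Trav7-4 and Trbv13-2 spread more in PD-1int and PD-1hi than in naive, with SDs in PD-1hi of 1.20, 0.90 and 0.91 against 0.31, 0.12 and 0.24 in naive.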

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

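The tests of the first pattern below were designed after the spread of the receptor segments was seen and those of the second after the Ighm values were seen; for the third, the prediction was written before its test was run. In each subset of 4 arrays, Dixon's gap of the farthest array over the range was computed for the 212 genes named in the text or drawn as receptor segments, and for the 29 list means. It exceeded the 95% value for 4 samples in 54 of 964 groups; chance alone does this in about 1 in 20 groups, here about 48. Each is a sample far from the other 3, given below with its ratio.

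Among naive arrays the far array was replicate 1 for Zbp1 (0.864). Replicate 2 of naive lay apart for Melk (0.873). Replicate 3 of naive lay apart for Ctla2b (0.955), Kif11 (0.969), Klra9 (0.933) and Klrc2 (0.943). Replicate 4 of naive lay apart for Ms4a1 (0.853), S100a6 (0.931), Trav3-4 (0.848) and the mean of the chemokine receptors list (0.901). Among memory arrays the far array was replicate 1 for Ccl5 (0.837) and Cflar (0.888). Replicate 2 of memory lay apart for Cd8a (0.880), Cd28 (0.863), Rps19 (0.857) and Klf3 (0.953). Replicate 3 of memory lay apart for Itgae (0.845), Ctla4 (0.854), Ms4a6c (0.842), Slco3a1 (0.965) and Trav7-4 (0.851). Replicate 4 of memory lay apart for Bbc3 (0.944), Ms4a1 (0.870) and the mean of the B-cell and CLL-cell marker list (0.854). In PD-1int the far array was replicate 1 for Ccr9 (0.887), Isg15 (0.866), Rpl13 (0.946) and Zdhhc2 (0.833). Replicate 2 of PD-1int lay apart for Cd8a (0.887), Maf (0.906), Xbp1 (0.852) and Cmpk2 (0.904). Replicate 3 of PD-1int lay apart for Treml2 (0.870), Lag3 (0.863) and the mean of the chemokines list (0.869). Replicate 4 of PD-1int lay apart for Ccl5 (0.909), Cst3 (0.852) and Cd200r1 (0.859). In PD-1hi the far array was replicate 1 for Dhx58 (0.887), Jun (0.890), Igtp (0.834), Ms4a6c (0.980) and Kif20a (0.932). Replicate 2 of PD-1hi lay apart for Klrk1 (0.903), Pdk1 (0.886), Slc28a2b (0.846), Klrd1 (0.892) and Trav12-2 (0.897). Replicate 3 of PD-1hi lay apart for Itgae (0.840). Replicate 4 of PD-1hi lay apart for Ctla2a (0.933), S100a6 (0.945), Zbtb7b (0.926), Csf1r (0.853) and Rpl13 (0.964).

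The receptor variable segments deviated more from array to array in PD-1int and PD-1hi than in naive. If this were noise shared by all genes of that brightness, random lists matched on mean expression would spread as much. The deviation lay at the 100th percentile of 10000 such lists in both subsets, which excludes it. Same-numbered PD-1int and PD-1hi arrays had a mean r of 0.037 over all genes, which cannot exclude a batch limited to some probe sets. The segments also ranked high in naive (97.7) and memory (93.9), so noise particular to their probe sets stays open. Clones shared by the 2 subsets of a mouse would make same-numbered arrays deviate alike in these segments: the mean r was 0.793, and 2 of 24 pairings were as high or higher (exact one-sided p = 0.0833, Benjamini-Hochberg adjusted p = 0.250 over 6 pairs of subsets), so this stays open. Expanded clones that differ between mice may explain the spread, but receptor sequences were not used here and the labels do not tell mice apart.

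Ighm, the heavy chain of IgM, was bright in naive and memory and lower in both PD-1 subsets. B or CLL cells left in the naive and memory sorts would carry other B-cell transcripts along, yet the 6 other markers abundant in B cells changed by a median of -0.125 from naive to PD-1hi, and Cd79b, the most changed, by -0.97, which this explanation cannot produce beside a change of -3.68 in Ighm. A single deviating probe set is excluded as well, since the next brightest of the 7 Ighm probe sets changed by -2.16; the other 5, with means of at most 7.51, changed by at most 0.15 either way, and the mean of all 7 by -0.85. Transcription of the locus by T cells themselves was not tested.

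Up to 16 of 29 gene lists passed camera with its preset correlation even when a comparison's 8 arrays were split arbitrarily. If list genes were correlated beyond the preset, an estimated correlation would remove these calls. Other splits then had at most 1. Uneven splits keep part of the subset difference, which may also yield such calls, so the cause stays open. No biological explanation was tested.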

How the results depend on the processing

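The alternatives were fixed before the data were seen, except that the inhibitory receptor and central memory lists were later repeated without Pdcd1 and Il7r, with no call changed. For the 12 counts of genes changed, 190 of 192 alternative values stayed within 1.5 times the main value. The exceptions were 2 values of the count for PD-1hi against PD-1int, each with 1 array left out: 470 without PD-1int replicate 1 and 474 without PD-1hi replicate 4, against 734 with all arrays. Over all 8 such fits that count ran from 470 to 751, and leaving out an array lowers the number of samples; the cause was not tested. With all arrays it ran from 582, in a fit of only the 8 arrays compared, to 885 without the 40% dimmest genes. Leaving out 1 array gave 2091 to 2560 genes for memory against naive, 4505 to 4814 for PD-1int against naive, 5540 to 5750 for PD-1hi against naive, 3040 to 3372 for PD-1int against memory and 4394 to 4596 for PD-1hi against memory.

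Deviations of same-numbered arrays from their subset means had r above 0.1 in 2 of 24 pairs (median 0.036), so arrays were not paired. The same number gave the highest r in 14 of 24, more than chance gives, so pairing stays open. With the number as a block the 6 counts were 2633, 5025, 6027, 748, 3576 and 4866. Klrc1 (adjusted p = 0.0754) and Pfkp (0.0550) in PD-1hi against PD-1int, and the B-cell (0.0508) and CD4 (0.0601) lists in PD-1hi against memory, then did not pass, whereas Lyz2 in PD-1hi against naive (0.0393) and Cd44 in PD-1int against memory (0.0275) did; no other call in the text changed.

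For the 174 list tests, 3144 of 3306 alternative results kept their direction and their side of the threshold, 116 lost significance, 45 gained it and 1 reversed. An estimated correlation ended 44 calls and camera on ranks 23, while fry, which compares a list with no other genes, added 29. The reversed result was cytokine receptors in PD-1int against naive: camera with the preset did not pass (adjusted p = 0.529, toward higher), whereas fry gave an adjusted p of 0.0079 toward lower. The list had a median log2 difference of 0.11 and a mean of -0.02; the cause was not tested. For the 708 results on single named genes, 10950 of 11296 alternatives were unchanged, 332 lost significance, 14 gained it and none reversed.

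The spread of receptor variable segments in PD-1int over naive was 0.146 with all segments and 0.14 with squared deviations, both past the threshold. It was 0.35 with Trbv segments only, a single segment, and 0.045 with the upper segments by mean, neither past it. In PD-1hi over naive it was 0.354, 0.401, 0.426 and 0.204 in the same order, again with the last 2 short of the threshold; the cause was not tested. Leaving out each replicate number in turn gave 0.067 to 0.22 for PD-1int and 0.254 to 0.403 for PD-1hi. Those tests set 3 arrays against 3, where the smallest exact p is 0.1, so none could pass.

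The files carry no background level or detection call, so signal over background cannot be given. Without the 40% dimmest genes, counts at the 2-fold limit were 388, 983, 1317, 104, 550 and 959 in the order of the comparisons above (memory, PD-1int and PD-1hi against naive, PD-1hi against PD-1int, PD-1int and PD-1hi against memory).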

Other observations

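The values for Cd22 were picked out after they were seen, and the segment pairing test was designed after the spread was seen. Cd22, an inhibitory receptor best known from B cells, had log2 means of 6.29 in naive, 9.50 in memory, 8.03 in PD-1int and 7.13 in PD-1hi, while Cd79a, Ms4a1 and Pax5 stayed within a narrow range.

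The pairing of arrays by number was tested on the 6 receptor segments for all 6 pairs of subsets. For memory with PD-1int the mean r was 0.334, the highest of the 24 pairings (exact one-sided p = 0.0417, adjusted 0.250), and for PD-1int with PD-1hi it was 0.793. None of the 6 passed after Benjamini-Hochberg adjustment. The smallest p that 24 pairings allow is 0.0417, so none could pass unless all 6 reached it at once.

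Every count was recomputed for all 35 splits of a comparison's 8 arrays into 4 and 4; for gene counts and lists with the preset correlation this was judged after the counts were known, and for lists with an estimated correlation the prediction was written before. For memory against naive only 1 of 35 splits, the real one, reached 2601 genes (highest other 1) or 422 at least 2-fold (highest other 0). For PD-1int against naive 1 of 35 reached 5037 genes (highest other 0) or 1028 (0), and for PD-1hi against naive 1 of 35 reached 6020 (0) or 1373 (0). For PD-1hi against PD-1int 1 of 35 reached 734 (highest other 5) or 105 (3), for PD-1int against memory 1 of 35 reached 3584 (1) or 585 (1), and for PD-1hi against memory 1 of 35 reached 4868 (0) or 1014 (0). Mixed splits blur a difference, so all 12 counts show only that the subsets differ.

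The number of lists passing separated the real split less well with the preset correlation. It was 16 against a highest other of 15 for memory against naive, 19 against 16 for PD-1int against naive, 17 against 15 for PD-1hi against naive, 17 against 15 for PD-1int against memory and 20 against 15 for PD-1hi against memory, each reached by 1 of 35 splits. For PD-1hi against PD-1int 2 of 35 splits gave 13 lists, so that number does not set the real split apart. With an estimated correlation the real split was alone, 1 of 35, in all 6 comparisons: 10 lists against 1, 14 against 1, 11 against 0, 8 against 0, 9 against 0 and 6 against 0, in the order memory, PD-1int and PD-1hi against naive, PD-1hi against PD-1int, and PD-1int and PD-1hi against memory. This again shows only that subsets differ.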
